A study of Mus musculus with 9 samples.

How the data were processed

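RNA was sequenced from sorted mouse bone marrow-derived macrophages in 9 libraries, 3 each from monoculture, co-culture with DRG neurons and TGF-β at 0.02 ng/ml. Libraries were made from 10 ng RNA with a stranded SMART-Seq kit, per the labels' protocols. The deposited table gives 1 signal value per gene and library, and per the submitters' processing notes the tools were bcl2fastq 2.20, STAR 2.7.3, DESeq2 1.24.0 and R 3.6.1 with build mm10. The notes give these tools no role or order, and the counting program, its use of strand, the annotation and any filter are not stated. The deposited signal values were read from the numbers themselves as gene read counts divided by 1 size factor per library: in each column every value was a whole multiple of the smallest (100% within 0.05). DESeq2 size factors recomputed from the recovered reads differed from these by at most 1.16e-09 of their value. Genes at 0 in all 9 libraries are not in the table. All 9 columns were matched to samples by the labels' own column names.

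The test was limma 3.58.1 with trend and robust empirical Bayes in R 4.3.3, on log2 of the value plus 10. Genes with a value of at least 10 in at least 3 libraries were tested, 16328 of 24607. All 9 libraries went into 1 fit with the group as the only factor, and co-culture against monoculture, TGF-β against monoculture and co-culture against TGF-β were contrasts of that fit. The p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at adjusted p under 0.05. "Rose" and "fell" are used for called genes. Fold changes are log2 with the standard error of the fit, levels are the mean ± SD of 3 normalized counts, and the added 10 makes fold changes of low genes smaller than the ratio of their means. Before the files were seen an edgeR quasi-likelihood test on counts had been planned; since the values are scaled, limma took its place and edgeR 4.0.16 on the recovered reads became an alternative.

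Depth ranged from 46.8 to 308.8 M reads (M, 1e6), and 1 read was worth 0.346 to 2.27 normalized counts. In simulated data drawn from the libraries' own means and depths with known changes among 16328 genes, 24%, 63% and 78% of genes changed by log2 0.5, 1 and 2 were recovered for co-culture against monoculture and 28%, 63% and 78% for TGF-β against monoculture, with 6 and 11 calls among 16108 unchanged genes. A planted list was called and 0 of 26 unchanged lists were. The simulated genes varied independently of each other, whereas the estimated correlation within the real lists reached 0.523. The simulation therefore cannot show how often lists of genes that vary together are called without an effect. A gene with 0 reads in a group has an upper limit of 3 reads (95% confidence), so for such genes levels are given and no fold.

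Gene lists (27, with 528 of their 556 genes in the table) were written from general knowledge before the data were examined: microglia, TGF-β targets, TGF-β pathway, Lyve1-high macrophages, MHC class II, inflammatory mediators, interferon response, alternative activation, cholesterol synthesis, LXR and efflux, lipid-associated macrophages, lysosome, glycolysis and hypoxia, respiratory chain, cell cycle, immediate early and stress genes, matrix proteases, axon guidance and trophic factors, pan-macrophage genes, and markers of sensory neurons, glia, fibroblasts, endothelium, neutrophils, dendritic cells, monocytes, and lymphoid and mast cells. The 26 with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with a correlation estimated per list and the rotation test fry. Member counts use the adjustment over all genes; where no second count is given, adjustment over the list alone gave the same counts.

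Genes named in the text were fixed by a rule before the data were examined. It took 16 set genes (the sort antigens, Cx3cr1, TGF-β pathway and microglia or tissue macrophage genes). It took the 8 rising and 8 falling called genes of largest fold change per comparison with above-median level and no overlap between groups, leaving out numbered gene models, mitochondrial, ribosomal protein, histone and receptor segment genes. It also took the 4 members of smallest p per list. Pmepa1 in co-culture, Selplg, Bambi, Xylt1, Pltp, Plin2, Abcg1, Srebf1, Srebf2, Gbp3, Cd14, Sirpa, Cd109, Spn, Gm23935, Yam1, the Y-linked genes and Xist were named after their values were seen, as exceptions to a list or as controls. Gene symbols are those of the table; 24335 of 24607 identifiers matched GENCODE M21 (mm10), where 1722 symbols have changed, such as Emr1 to Adgre1. How reads shared by close paralogs (Ctla2a, the Ms4a, Oas, Oasl, Gbp and H2 genes) were assigned is not stated.

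The 2 effects against monoculture share their control libraries. Their covariance was therefore set beside 100 simulations without effect that shared a simulated control group. All 9 libraries were drawn gene by gene from the monoculture means, the size factors and the fitted dispersions. The simulations thus hold no variation shared by genes within a library. The overlap was set beside the number for independent sets, since the simulations call too few genes to overlap. As 3 controls cannot be divided into 2 parts of at least 2, part of the excess over the simulations may still come from the shared controls.

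Alternatives set before the data were examined were total count scaling, no filter, a filter of 1 CPM (counts per 1e6 reads) in every library of a group, edgeR on DESeq2 size factors, DESeq2 1.42.0 and limma-voom on recovered reads, fits of only the 2 groups compared, the replicate number as a block, thresholds of adjusted p 0.01 or a log2 fold change of 1, camera with an estimated correlation, fry, and leaving out each library. Added after the data were seen were edgeR on recovered reads, TMM scaling, added values of 1 and 50, thinning to the shallowest library, mouse sex as a block, leaving out monoculture 1 and TGF-β 2 together, and leaving out each library with the same 16328 genes tested. In the planned fits without 1 library the filter was redone, so genes seen only in the 3 libraries of a group dropped out when 1 of them was left out. Figures were drawn with Python 3.11.15. No library was left out of the test.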

Results

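Macrophages grown from the bone marrow of Cx3cr1-gfp/+ mice, which carry green fluorescent protein at the locus of the fractalkine receptor Cx3cr1, were compared under 3 conditions. The series title states that sensory neurons give nearby macrophages their local identity through transforming growth factor beta (TGF-β). Monoculture, co-culture with sensory neurons of the dorsal root ganglion (DRG) and exposure to 0.02 ng/ml TGF-β were each labeled with a time of 5 days and with macrophage colony-stimulating factor (M-CSF) at 50 ng/ml. Whether the 5 days are the differentiation before treatment, the treatment itself or both is not stated. The cells were sorted on CD11b (gene Itgam) and CD64 (gene Fcgr1), and 3 libraries were sequenced per condition. The design text gives 3 mice as the source; whether the same 3 mice served every condition is not stated. The normalized counts of 24607 genes came from 73.4, 91.9 and 135.6 M reads (M, 1e6) for monoculture 1 to 3. Depth was 308.8, 133.8 and 166.1 M for co-culture 1 to 3, and 151.6, 55.9 and 46.8 M for TGF-β 1 to 3. Reads were seen for 18410 to 21648 genes per library.

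The co-culture libraries separated from all others on the first principal component, which held 61.2% of the variance. Their scores were 62.5 to 71.3, against -23.8 to -24.6 with TGF-β and -39.3 to -44.9 in monoculture, so TGF-β-treated macrophages lay between the other groups but near monoculture. Mitochondrial ribosomal RNA took 10.4 to 11.5% of reads in monoculture, 12.3 to 15.0% in co-culture and 11.5 to 14.9% with TGF-β, with every monoculture library below all others. The noncoding RNA genes Gm23935 and Yam1 took 3.69 to 10.8% and 0.505 to 2.82%, highest in monoculture 1 and TGF-β 2.

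In the co-culture libraries the genes by which resting microglia, the macrophages of the brain, are recognized were higher. Fibroblast markers (median 4.90) and reads of the other sex, given below, were higher in the same libraries. Of the 17 fibroblast markers, 6 passed the filter outside co-culture. The rest were tested only because co-culture was high, so this median is not a fair measure of the rise. The scavenger-type Fc receptor-like gene Fcrls rose from 618 ± 119.9 normalized counts in monoculture to 103820.0 ± 6581 in co-culture (mean ± SD, n = 3 each; log2 fold change 7.38 ± 0.12, estimate ± SE; adjusted p = 7.59e-14). Cx3cr1, the receptor for the neuronal chemokine fractalkine, rose from 314 ± 6.02 to 9859 ± 1787 (4.91 ± 0.16, adjusted p = 3.33e-10). The purinergic receptor P2ry12, with which microglia sense nucleotides from neurons, rose from 747 ± 49.4 to 5251 ± 399.5 (2.80 ± 0.11, adjusted p = 3.33e-10). Tmem119, a membrane protein used to tell microglia from blood-derived macrophages, rose from 26.1 ± 22.8 to 1364 ± 477 (5.36 ± 0.43, adjusted p = 7.04e-07). The complement gene C1qa rose from 12976 ± 1792 to 95551 ± 1494 (2.89 ± 0.11, adjusted p = 2.06e-10). Of 22 tested genes of the homeostatic microglia signature, 17 rose and 2 fell, with a median log2 fold change of 1.95 (camera adjusted p = 1.19e-13; adjusted p = 0.205 with an estimated correlation). The 2 that fell were Trem2, a lipid-sensing receptor of microglia and tissue macrophages (-0.53 ± 0.08, adjusted p = 1.78e-04), and Selplg, the selectin ligand (-0.61 ± 0.08). Sall1, the transcription factor that marks brain microglia, had a mean of 0.482 in co-culture and 0 elsewhere and was not tested. By identifier and mm10 position these genes are Fcrls (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), P2ry12 (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871) and Tmem119 (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516), all on the minus strand.

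**Figure D1:**
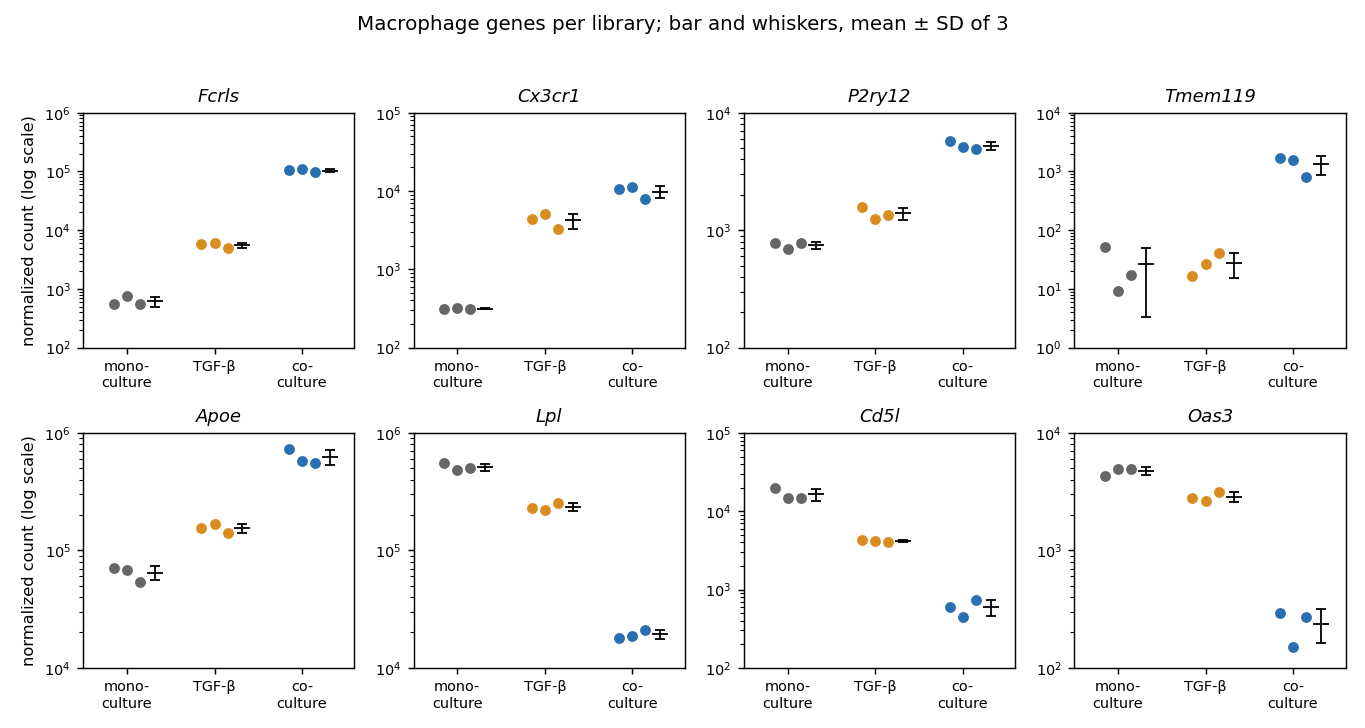
Normalized counts of Fcrls, Cx3cr1, P2ry12, Tmem119, Apoe, Lpl, Cd5l and Oas3 in monoculture, co-culture and TGF-β macrophages. Points are single libraries, bars and whiskers are mean ± SD of 3, and the axes are logarithmic.

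Genes listed beforehand as induced by TGF-β through SMAD transcription factors rose in the co-culture libraries as well. Fibroblast markers also rose in these libraries (median log2 fold change 4.90), though only 6 of the 17 passed the filter outside co-culture. Among 30 tested targets 21 rose and 3 fell (median log2 fold change 0.85; camera adjusted p = 1.15e-07; adjusted p = 0.212 with an estimated correlation). Pmepa1, which encodes a membrane protein that restrains SMAD signaling, had the largest fold change of all tested genes, from 21.1 ± 15.0 to 21474 ± 2406 (9.55 ± 0.43, adjusted p = 4.80e-07). The inhibitory SMAD Smad7 rose from 575 ± 59.6 to 2362 ± 155 (2.02 ± 0.12, adjusted p = 1.55e-08), and Spsb1, a SOCS-box gene that limits TGF-β receptor signaling, by 4.26 ± 0.14. Thbs1, whose product thrombospondin 1 can activate latent TGF-β and which fibroblasts also make, rose from 577 ± 134 to 38259.7 ± 21865 (5.91 ± 0.39, adjusted p = 1.39e-05). The genes that fell were Eng, the co-receptor endoglin (-2.05 ± 0.11), Bambi, the decoy receptor (-0.85 ± 0.16), and Xylt1, a xylosyltransferase (-0.46 ± 0.11). Among ligands, receptors, activators and SMADs of the pathway, 8 of 18 rose and 5 fell, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.261; 0.00170 with the rotation test fry). The receptor genes Tgfbr1 (2.05 ± 0.11, adjusted p = 7.72e-09) and Tgfbr2 (1.02 ± 0.09, adjusted p = 6.89e-07) and the signal transducer Smad3 (1.12 ± 0.09) rose. From the target list, the latent TGF-β-activating integrin subunit Itgb5 (1.95 ± 0.10) rose too. The ligand gene Tgfb1 did not pass the test (-0.03 ± 0.08, adjusted p = 0.825).

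Lipid transport genes moved in both directions in the co-culture libraries. Fibroblast markers (median log2 fold change 4.90, with 6 of 17 passing the filter outside co-culture) and reads of the other sex were also higher there. Apoe, which encodes the main lipid carrier secreted by macrophages, rose from 64730.5 ± 9211 to 624838 ± 95589 (3.27 ± 0.13, adjusted p = 4.93e-10). Its neighbor Apoc2 rose by 3.17 ± 0.15, the cholesterol exporter Abca1 by 2.50 ± 0.11 and the fatty acid desaturase Scd2 by 1.76 ± 0.10. Lpl, the lipase that frees fatty acids from lipoproteins, fell from 512481 ± 35268 to 19338 ± 1619 (-4.73 ± 0.10, adjusted p = 6.99e-13). The fatty acid and scavenger receptor Cd36 fell as well (-3.16 ± 0.16), as did the galectin Lgals3 (-2.01 ± 0.13) and the osteoclast protease Ctsk (-2.14 ± 0.20). Of 15 targets of the oxysterol receptor LXR and efflux genes, 9 rose and 4 fell (camera adjusted p = 0.00541; adjusted p = 0.225 with an estimated correlation). The 4 were Pltp (-2.68), Plin2 (-1.12), Abcg1 (-0.51) and Srebf1 (-0.45), which act in lipid transfer, storage, efflux and synthesis. Of 21 cholesterol synthesis genes 13 rose and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 2.16e-04; adjusted p = 0.456 with an estimated correlation). Mvd (1.04 ± 0.12) and Hmgcs1 (0.78 ± 0.09) were among them, and the gene that fell was the regulator Srebf2 (-0.26 ± 0.09). Lipid-associated macrophage genes fell, 12 down and 7 up of 20 (camera adjusted p = 0.0133; adjusted p = 0.476 with an estimated correlation).

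Interferon-stimulated genes were lower in co-culture. The antiviral oligoadenylate synthetase Oas3 fell from 4735 ± 349 to 238 ± 75.9 (-4.31 ± 0.20, adjusted p = 1.13e-08), and the related Oasl1 (-2.96 ± 0.19) and Oasl2 (-2.69 ± 0.11) fell too. Of 27 tested, 21 fell and 2 rose (median -1.51; camera adjusted p = 1.83e-11; adjusted p = 0.225 with an estimated correlation). The 2 that rose were the guanylate-binding protein Gbp3 (1.84 ± 0.14) and tetherin, Bst2 (0.57 ± 0.11). Among 18 inflammatory mediators 8 fell and 5 rose, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.175). The signaling adaptor Traf1 fell (-3.37 ± 0.18), as did the chemokine Ccl3 (-0.98 ± 0.11), and the cytokine Osm rose (1.63 ± 0.14). The interleukin gene Il1b was listed at 0 reads in all 3 monoculture libraries and averaged 263 ± 40.4 in co-culture. Glycolysis and hypoxia genes fell, 14 of 24 with 2 rising, or 15 and 2 adjusted over the list alone (median -0.48; camera adjusted p = 0.00541; adjusted p = 0.559 with an estimated correlation; 0.0572 with the rotation test fry). The phosphofructokinase Pfkp was among them (-1.72 ± 0.09). The exceptions were hexokinase 2, Hk2 (1.47 ± 0.09), and the regulator Pfkfb3 (1.18 ± 0.10).

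General macrophage genes moved in both directions or did not pass the test. The M-CSF receptor gene Csf1r (0.06 ± 0.10, adjusted p = 0.696) and the sort antigens Itgam (-0.12 ± 0.09, adjusted p = 0.387) and Fcgr1 (0.05 ± 0.10, adjusted p = 0.778) did not pass the test. Emr1 (now Adgre1, the F4/80 antigen) fell (-0.69 ± 0.11, adjusted p = 2.26e-04). Of 20 pan-macrophage genes 9 rose, led by the sialic acid-binding receptor Cd33 (3.38 ± 0.12) and Aif1, the IBA1 antigen (3.11 ± 0.12). The 3 that fell were the endotoxin co-receptor Cd14 (-1.11 ± 0.18), Emr1 and the CD47 receptor Sirpa (-0.26 ± 0.09). This list passed with camera adjusted p = 0.0443 (adjusted p = 0.456 with an estimated correlation) and not without monoculture 3 (adjusted p = 0.146), with the replicate number as a block, or without co-culture 1 or 3 when the same genes were tested (0.0551, 0.0867). Genes of perivascular Lyve1-high macrophages gave 7 higher and 3 lower of 16, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.203; 0.00812 with fry). The mannose receptor Mrc1 (1.12 ± 0.12) and the transglutaminase F13a1 (4.60 ± 0.25) rose, the folate receptor Folr2 fell (-2.20 ± 0.12), and the hyaluronan receptor Lyve1 did not pass (0.52 ± 0.44, adjusted p = 0.425). MHC class II presentation genes gave 7 higher and 3 lower of 14 (camera adjusted p = 0.113). The costimulator Cd86 (2.69 ± 0.15) and the peptide loader H2-DMb2 (2.72 ± 0.33) were higher, and the list passed with edgeR on the recovered reads (adjusted p = 0.0292). Alternative activation genes gave 6 higher and 5 lower of 14 (camera adjusted p = 0.364). The interleukin 4 receptor Il4ra was higher (2.78 ± 0.11) and the lectin Clec10a lower (-2.91 ± 0.18). This list, with a median of 0.49, passed with edgeR (adjusted p = 0.0107) and where 1 CPM was required in every library of a group (adjusted p = 0.0371, median 2.78).

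Of the broader cell functions, none passed camera. Lysosome genes gave 12 higher and 5 lower of 30 (camera adjusted p = 0.476; the acid lipase Lipa -0.98 ± 0.09). Cell cycle genes gave 11 and 5 of 30, or 14 and 6 adjusted over the list alone (adjusted p = 0.476; the replication clamp Pcna -1.08 ± 0.09). Immediate early and stress genes gave 9 and 9 of 24 (adjusted p = 0.820), with the cytokine signal inhibitor Socs3 up (4.11 ± 0.17) and the stress factor Atf3 down (-1.74 ± 0.11). Respiratory chain genes gave 1 and 1 of 26 (adjusted p = 0.820; median -0.03, mean 0.01). The cytochrome oxidase subunit Cox5a rose (0.51 ± 0.10) and Ndufa4 fell (-0.73 ± 0.16). Axon guidance and trophic genes gave 7 and 8 of 22, or 8 and 8 adjusted over the list alone (adjusted p = 0.648; median -0.10, mean 0.08). The semaphorin Sema6d rose (2.05 ± 0.17) and Sema3c fell (-4.11 ± 0.35). Matrix proteases and inhibitors gave 5 and 8 of 18, or 6 and 8 adjusted over the list alone (adjusted p = 0.669; median -0.14, mean 0.52). The list test leaned downward, whereas the rotation test fry pointed upward (adjusted p = 0.00895). Mmp14, the membrane-anchored collagenase, rose from 89.1 ± 10.9 to 27180.0 ± 4697 (8.09 ± 0.14, adjusted p = 7.59e-14).

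Transcripts of other cell types, which the sort on CD11b and CD64 selects against as whole cells, also appeared in co-culture. All 17 tested fibroblast markers rose (median 4.90; camera adjusted p = 5.82e-14; adjusted p = 0.212 with an estimated correlation). Of these, 6 passed the filter on the monoculture and TGF-β libraries alone, and the other 11 were tested only because co-culture was high. The collagen gene Col1a2 rose from 28.8 ± 12.9 to 1984 ± 326 (5.73 ± 0.32) and the matrix gene Fbln2 from 5.62 ± 5.24 to 1202 ± 130.1 (6.33 ± 0.31). Glial markers gave 10 higher and 5 lower of 17 (camera adjusted p = 0.113), or 1 and 5 of the 8 that passed the filter outside co-culture. The Schwann cell receptor Ngfr was listed at 0 reads in all 3 monoculture libraries and averaged 234 ± 26.0 in co-culture. The adhesion gene L1cam, also expressed by myeloid cells, fell (-3.09 ± 0.10). Of 5 sensory neuron markers the tubulin gene Tubb3 alone rose (1.68 ± 0.41, adjusted p = 0.00562; list adjusted p = 0.424). The donors of replicate 1 were male and those of replicates 2 and 3 female in every condition by Y-linked and Xist reads. The Y-linked helicase gene Ddx3y had 57.8 and 58.5 counts in the female co-culture libraries and 0 in the other female libraries. The 4 Y-linked genes examined stood at 0.287 to 0.726% of their male level in female co-culture libraries, and the X-inactivation transcript Xist at 0.402% of its female level in the male one. The increases of the fibroblast markers summed to 0.0121% of co-culture reads. The matrix and protease genes Fn1 (7.26 ± 0.56), Mmp2 (6.06 ± 0.49) and Timp3 (4.03 ± 0.40), all of which fibroblasts express strongly, rose beside them. Endothelial (4 higher, 3 lower of 7; adjusted p = 0.883), neutrophil (3 and 1 of 5; 0.186), dendritic cell (3 and 0 of 8; 0.113) and monocyte markers (2 and 3 of 9, or 4 and 4 adjusted over the list alone; 0.930) did not pass camera, but neutrophil (0.00213) and dendritic cell markers (0.00895) passed fry. Cd4, the only tested lymphoid or mast cell marker and one that macrophages can express, rose by 1.80 ± 0.21.

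**Figure D2:**
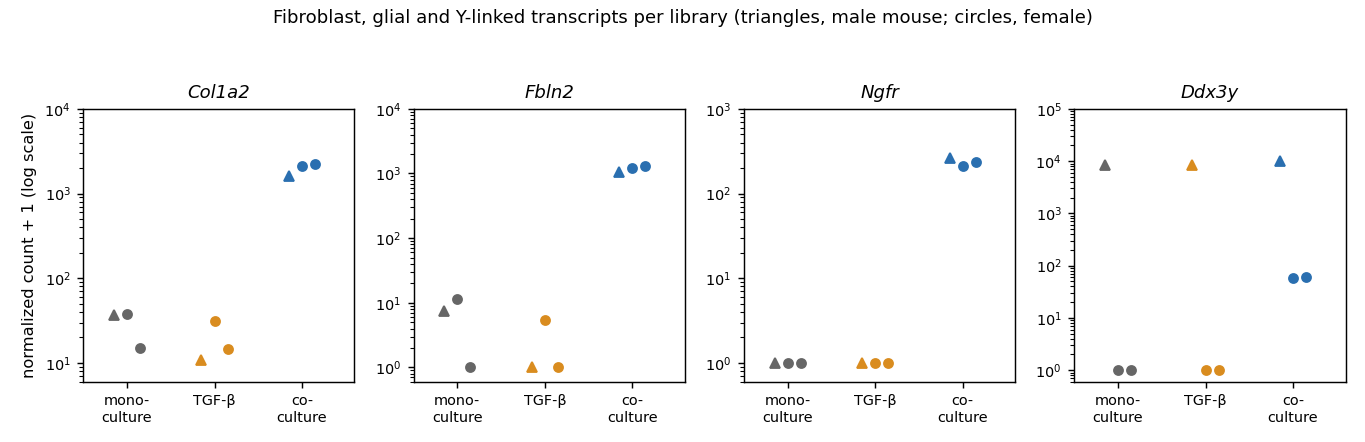
Normalized counts plus 1 of the fibroblast genes Col1a2 and Fbln2, the Schwann cell gene Ngfr and the Y-linked gene Ddx3y in each library. Triangles are libraries from male mice and circles are libraries from female mice.

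Across the transcriptome 5033 of 16328 tested genes differed between co-culture and monoculture, 2590 higher and 2443 lower, of which 1183 and 857 changed more than 2-fold. Without co-culture 1 the split was 1694 higher and 1996 lower with the filter redone, and 1979 and 2021 with the same genes tested. Without co-culture 2 it was 1705 and 1905, and 1980 and 1929. Among the largest further increases were Ctla2a, a protease inhibitor of immune cells (5.67 ± 0.33), the lectin receptor Clec4n (5.03 ± 0.18), the tetraspan gene Ms4a4a (4.86 ± 0.20) and the crosslinking enzyme Tgm2 (3.99 ± 0.16). Among the largest decreases were those of the pentraxin Nptx1 (-5.54 ± 0.48), the adhesion gene Flrt2 (-5.23 ± 0.24), the catenin Ctnnd2 (-5.11 ± 0.28) and Cd5l, a secreted macrophage survival factor that fell from 16547 ± 2897 to 597 ± 145 (-4.78 ± 0.16, adjusted p = 1.02e-09). Of the 26 lists 9 passed camera with a preset correlation. With an estimated correlation 0 lists passed, in this comparison and in both others.

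TGF-β alone raised part of the same microglia-type genes, by smaller amounts. Fcrls rose from 618 ± 119.9 in monoculture to 5610.0 ± 546 with TGF-β (n = 3 each; log2 fold change 3.17 ± 0.12; adjusted p = 9.09e-09) and Cx3cr1 from 314 ± 6.02 to 4217 ± 923 (3.68 ± 0.16, adjusted p = 1.59e-07). P2ry12 rose to 1387 ± 164 (0.88 ± 0.11, adjusted p = 5.44e-04). Gpr34, a lysophospholipid receptor of microglia, rose from 215 ± 48.6 to 820.5 ± 214 (1.88 ± 0.19, adjusted p = 2.20e-04), and C1qa to 29439 ± 2844 (1.19 ± 0.11). Tmem119 did not pass (0.20 ± 0.43, adjusted p = 0.893). Of the 22 microglia signature genes 12 rose and 0 fell, or 14 and 0 adjusted over the list alone (median 0.53; camera adjusted p = 5.62e-18; adjusted p = 0.102 with an estimated correlation).

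Outside that signature the bone marrow-homing chemokine receptor Cxcr4 (1.84 ± 0.19, adjusted p = 6.32e-04), the receptor kinase Axl, which clears apoptotic cells (1.72 ± 0.24, adjusted p = 0.00538), the chemokine Cxcl14 (1.69 ± 0.21, adjusted p = 0.00289) and the monocyte chemokine receptor Ccr2 (1.53 ± 0.20, adjusted p = 0.00102) rose. Mmp14 (1.99 ± 0.14), Cd33 (1.59 ± 0.12) and the inhibitory Fc receptor Fcgr2b (0.98 ± 0.11) rose too. Apoe increased to 154014 ± 13377 (1.26 ± 0.13, adjusted p = 1.79e-04), and Apoc2 by 1.21 ± 0.15. Cd5l fell to 4175 ± 127 (-1.97 ± 0.16, adjusted p = 7.82e-05) and Lpl to 234807 ± 18536 (-1.13 ± 0.10, adjusted p = 6.26e-05). The lectins Mgl2 (-2.19 ± 0.36) and Clec10a (-1.24 ± 0.18) and the peptide-processing enzyme Cpe (-1.38 ± 0.16) fell as well. The vascular growth factor receptor Kdr fell (-0.82 ± 0.13). Of the TGF-β target genes 5 rose and 1 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00891, 0.0661 without monoculture 1; adjusted p = 0.385 with an estimated correlation; median 0.07). Pmepa1 rose from 21.1 ± 15.0 to 417 ± 181 (3.79 ± 0.43, adjusted p = 0.00331) and Tgfbr1 by 0.88 ± 0.11 (adjusted p = 7.44e-04). The call for Smad7 (0.54 ± 0.12, adjusted p = 0.0267) ended without monoculture 1, monoculture 3, TGF-β 1 or TGF-β 2, and Tgfbr2 did not pass (0.16 ± 0.09, adjusted p = 0.437).

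Further lists passed with few single genes called. Cholesterol synthesis (2 higher, 0 lower of 21, or 8 and 0 adjusted over the list alone; camera adjusted p = 3.07e-06, 0.385 with an estimated correlation), cell cycle (1 and 0 of 30, or 5 and 1; 6.34e-05, 0.332), and respiratory chain genes (0 and 0 of 26; 6.66e-04, 0.424) were higher. So were MHC class II genes (2 and 0 of 14, or 4 and 0; 0.00143, 0.312), LXR targets (5 and 1 of 15; 0.00891, 0.332), pan-macrophage genes (3 and 0 of 20, or 5 and 2; 0.0385, 0.385) and dendritic cell markers (0 and 0 of 8, or 2 and 0; 0.0155, 0.332). Interferon-stimulated genes were lower (0 higher and 4 lower of 27, or 1 and 9; 6.49e-05, 0.385), as were glycolysis (0 and 3 of 24, or 0 and 4; 3.09e-04, 0.424), lipid-associated (1 and 4 of 20, or 1 and 6; 0.00833, 0.408), and axon guidance genes (0 and 1 of 22; 0.00891, 0.332). Lower too were inflammatory (0 and 0 of 18, or 0 and 2; 0.0301, 0.385) and matrix protease genes (1 and 0 of 18, or 1 and 4; 0.0301, 0.424). Leaving out TGF-β 3 ended the calls for LXR, lipid-associated, inflammatory, protease and dendritic lists. Leaving out TGF-β 1 ended those for inflammatory, protease, pan-macrophage and dendritic lists. The protease call also ended without monoculture 1, and the axon guidance and dendritic calls without monoculture 2. The pan-macrophage call also ended without monoculture 3 or co-culture 3, and the respiratory chain call ended without TGF-β 2. With fry, TGF-β target, interferon, inflammatory, cholesterol, glycolysis, lipid-associated, respiratory chain and protease lists did not pass. Where 1 CPM was required in every library of a group, MHC class II genes did not pass (camera adjusted p = 0.0507). Inflammatory, protease and pan-macrophage genes did not pass there either (0.0651 each). Protease genes also did not pass with edgeR on the recovered reads (0.172). The other 11 lists did not pass. Fibroblast markers gave 0 and 0 of 17 (adjusted p = 0.613), and monocyte markers gave a median of 0.05 and a mean of -0.01 (adjusted p = 0.815).

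**Figure D3:**
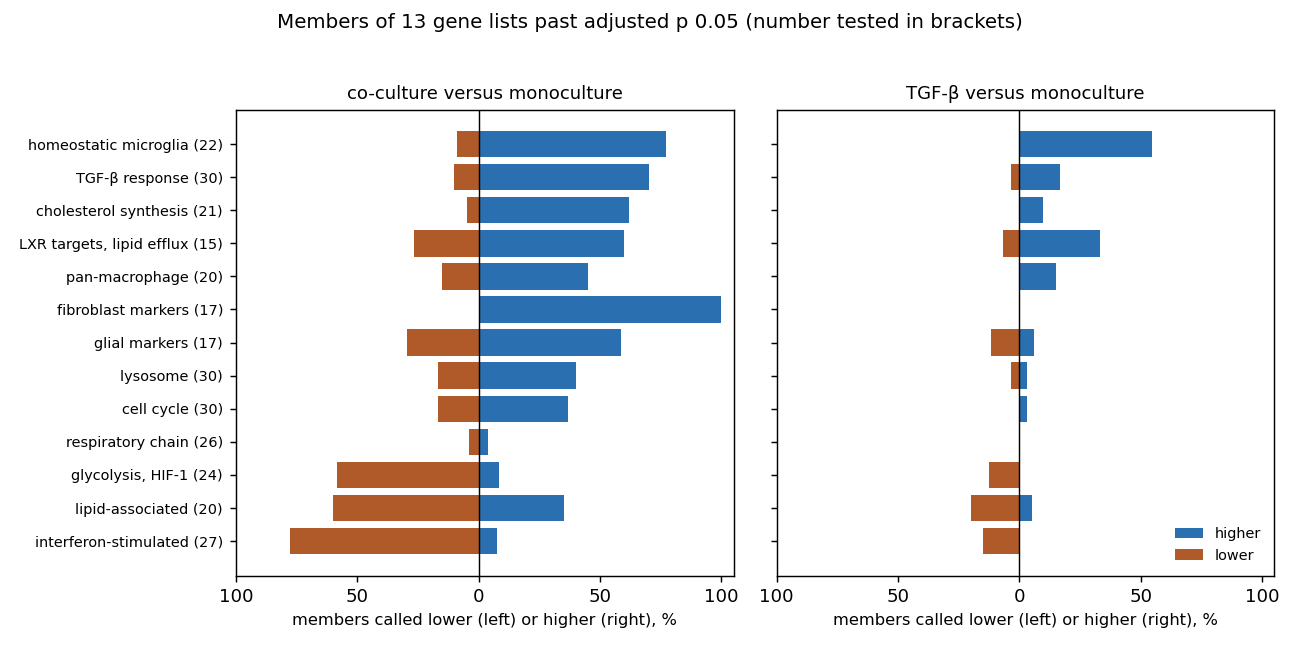
Percent of the tested members of 13 gene lists that were higher or lower in co-culture and with TGF-β, each against monoculture.

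In all, 412 genes differed between TGF-β and monoculture, 185 higher and 227 lower, with 64 and 47 beyond 2-fold. Itgam (-0.34 ± 0.09, adjusted p = 0.0795), Fcgr1 (-0.25 ± 0.10, 0.269), Csf1r (0.04 ± 0.10, 0.917), Emr1 (-0.39 ± 0.11, 0.0880), Tgfb1 (-0.13 ± 0.08, 0.508), Trem2 (0.07 ± 0.08, 0.757), Mrc1 (-0.40 ± 0.12, 0.103) and Lyve1 (-0.71 ± 0.44, 0.505) did not pass. The number of genes called was 268 without monoculture 1 (156 higher, 112 lower), 249 without monoculture 2 (145 and 104), 165 without TGF-β 1 (92 and 73), 248 without TGF-β 2 (125 and 123) and 935 without TGF-β 3 (496 and 439). It was 846 with DESeq2 on the recovered reads (398 and 448) and 150 (96 and 54) with monoculture 1 and TGF-β 2 both left out, where Pmepa1 no longer passed. Pmepa1 passed in every fit without 1 library, with log2 fold changes of 3.41 to 4.21.

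Set directly against TGF-β, co-culture gave higher genes of the microglia and TGF-β target lists. Fcrls was higher in co-culture by a log2 fold change of 4.21 ± 0.12 (n = 3 each; adjusted p = 5.27e-11), Tmem119 by 5.16 ± 0.43 (adjusted p = 1.74e-06), P2ry12 by 1.92 ± 0.11 (adjusted p = 2.62e-08) and Cx3cr1 by 1.23 ± 0.16 (adjusted p = 8.93e-05). Mmp14 (6.11 ± 0.14), Thbs1 (5.83 ± 0.39), Spsb1 (3.83 ± 0.14), Smad7 (1.48 ± 0.12), Tgfbr1 (1.17 ± 0.11) and Tgfbr2 (0.86 ± 0.09) were higher. So were Apoe (2.01 ± 0.13, adjusted p = 9.44e-08), Abca1 (2.37 ± 0.11), Mrc1 (1.52 ± 0.12) and the integrin Itgax, which codes for CD11c (3.05 ± 0.28). Of the TGF-β genes named here, Smad7 and Tgfbr1 had also been called higher with TGF-β alone, and Tgfbr2 had not passed. Thbs1 was at 601 ± 96.3 with TGF-β and 577 ± 134 in monoculture, and Spsb1 at 228 ± 2.52 and 166 ± 11.7. Lower in co-culture were Lpl (-3.60 ± 0.10, adjusted p = 3.66e-11), the ubiquitin hydrolase Uchl1, better known from neurons (-4.13 ± 0.12, adjusted p = 5.27e-11), Oas3 (-3.58 ± 0.20), Cd5l (-2.81 ± 0.16), Cd36 (-2.71 ± 0.16), Ccr2 (-1.03 ± 0.20, adjusted p = 0.00173), Trem2 (-0.61 ± 0.08) and the MHC class II invariant chain Cd74 (-0.78 ± 0.13).

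The microglia signature had 18 higher and 2 lower of 22 (median 1.20; camera adjusted p = 1.03e-11, 0.145 with an estimated correlation) and the TGF-β targets 20 and 2 of 30 (1.57e-08, 0.169). TGF-β pathway genes (9 and 2 of 18, or 9 and 3 adjusted over the list alone; 0.0140, 0.346), LXR targets (9 and 2 of 15, or 9 and 3; 0.00309, 0.210) and cholesterol synthesis genes (4 and 0 of 21; 0.0408, 0.679) were higher. Pan-macrophage (6 and 1 of 20, or 7 and 2; 0.0363, 0.379) and Lyve1-high macrophage genes (6 and 3 of 16, or 7 and 3; 0.0408, 0.281) were higher as well. So were fibroblast (17 and 0 of 17; 4.00e-17, 0.145) and glial markers (9 and 4 of 17; 0.0335, 0.480). Only 6 of the 17 fibroblast and 8 of the 17 glial markers passed the filter outside co-culture. Both calls thus rest in part on members tested only because co-culture was high. Interferon-stimulated (1 and 18 of 27, or 1 and 19; 1.97e-11, 0.226), lipid-associated (5 and 11 of 20; 0.0174, 0.492) and respiratory chain genes (0 and 2 of 26, or 0 and 1; 0.0335, 0.679) were lower. Inflammatory mediators had a median of -0.34 and a mean of 0.09 without passing (adjusted p = 0.490). Csf1r (0.02 ± 0.10, adjusted p = 0.902), Itgam (0.22 ± 0.09, 0.105), Fcgr1 (0.30 ± 0.10, 0.0513), Emr1 (-0.30 ± 0.11, 0.0608), Tgfb1 (0.10 ± 0.08, 0.423) and Lyve1 (1.22 ± 0.44, 0.0585) did not pass. In total 4128 genes differed, 2189 higher and 1939 lower in co-culture. With scaling by total count the split was 2331 and 1271. With the filter redone the count was 2735 without co-culture 1 (1337 higher, 1398 lower) and 2669 without co-culture 2 (1339 and 1330). With the same genes tested it was 3039 (1604 and 1435) and 2959 (1603 and 1356). The cholesterol synthesis, Lyve1-high, respiratory chain and glial lists did not pass with edgeR on the recovered reads, nor pan-macrophage genes without TGF-β 3. With the filter redone, the Lyve1-high call held in 4 of 9 fits without 1 library and the glial call in 5 of 9. The cholesterol synthesis and respiratory chain calls held in 7 of 9 each. Total count scaling ended the Lyve1-high, respiratory chain and glial calls, and fits without a filter ended the Lyve1-high call. Requiring 1 CPM in every library of a group ended the calls for TGF-β pathway, lipid-associated, Lyve1-high and respiratory chain genes. It left 10 of the 17 glial markers, which did not pass (adjusted p = 0.968). Alternative activation genes, which did not pass (median 0.65), passed with edgeR (adjusted p = 3.02e-04).

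The effects of co-culture and of TGF-β ran in the same direction for most genes that TGF-β changed. Of its 412 genes, 379 (92.0%) also changed in co-culture in the same direction, 162 higher and 217 lower. For independent sets 29.3 and 34.0 were expected, which does not allow for the monoculture libraries that the 2 comparisons share. Cx3cr1, Fcrls and Apoe were among the genes raised in both and Lpl and Cd5l among those lowered in both. For 306 of the 412 the change in co-culture was larger by direct test. The median absolute log2 fold change with TGF-β was 0.67. The median change in co-culture, counted as positive in the direction of the TGF-β change, was 1.64. Of the rest 31 were not called in co-culture and 2 moved in opposite directions, the TGF-β co-receptor Cd109 (0.82 ± 0.12 with TGF-β, -0.49 ± 0.12 in co-culture) and the sialophorin Spn (0.49 ± 0.10, -0.64 ± 0.10). The covariance of the fold changes over all 16328 genes was 0.155. In 100 simulations without effect, with the control group simulated too, it was 0.0351 on average (0.0316 to 0.0388). The correlation was 0.537 against 0.502 (highest 0.532). The share of genes with the same sign in both comparisons was 67.8%, against 66.7% on average in the simulations (highest 67.7%). The overlap of 379 was 243 without monoculture 1, 232 without monoculture 2, 153 without TGF-β 1, 232 without TGF-β 2, 658 without TGF-β 3, 701 with DESeq2 and 136 with monoculture 1 and TGF-β 2 both left out. The covariance was 0.0972 and 0.264 with 50 or 1 added in place of 10, and 0.330 to 0.359 with count models.

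**Figure D4:**
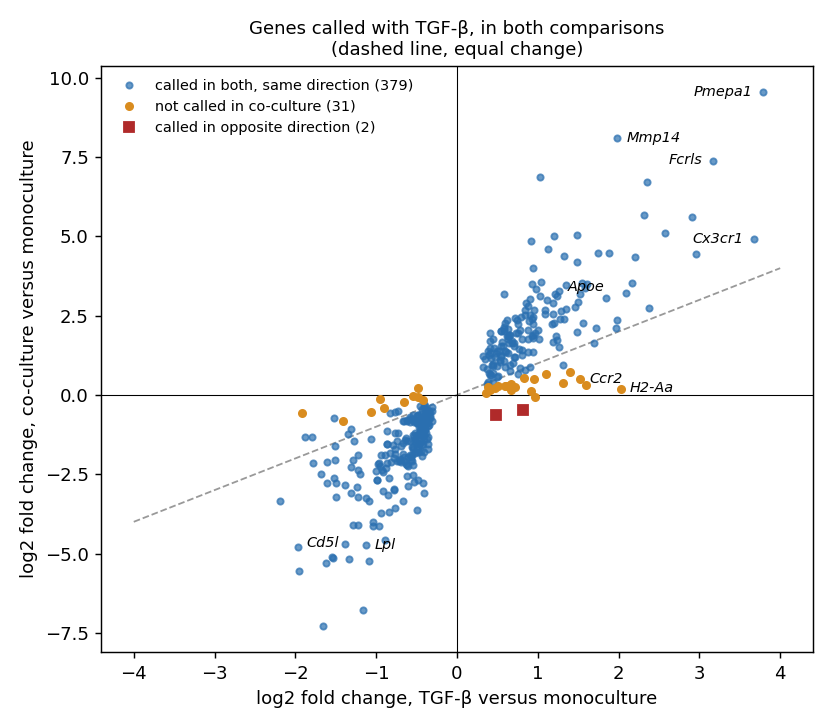
Log2 fold changes of the 412 genes changed by TGF-β, with TGF-β against monoculture on the horizontal axis and co-culture against monoculture on the vertical axis. Colors show the genes changed in the same direction in co-culture (379), not called there (31) or changed in the opposite direction (2); the dashed line marks equal change.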

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

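Of the alternatives, edgeR on recovered reads, TMM scaling, added values of 1 and 50, thinning, the sex block, leaving out monoculture 1 with TGF-β 2, and leaving out each library with the same genes tested were chosen after the results had been seen. No gene called both in the test and in an alternative changed sign; signs of genes that lost their call were not counted. For co-culture against monoculture the count of changed genes stayed within 1.5 times 5033 except at a 2-fold minimum (2040), and it was 3610 to 5468 with each library left out, while the genes higher (2590) were 1694 to 2825 and those lower (2443) 1905 to 2643. For TGF-β against monoculture (412) it was 170 at adjusted p under 0.01, 111 at a 2-fold minimum, 846 with DESeq2, 150 without monoculture 1 and TGF-β 2, and 165 to 935 with each library left out. For co-culture against TGF-β (4128) it was 2650 at adjusted p under 0.01, 1527 at a 2-fold minimum, and 2669 to 4601 with each library left out, with 1337 to 2450 higher and 1330 to 2151 lower. The filter was redone in these fits; with the same genes tested the counts were 3909 to 5464, 165 to 939 and 2959 to 4601, and the overlap below was 153 to 661. Stricter thresholds lower counts by construction. Fewer libraries weaken the test, yet some counts rose, such as 5173 for co-culture against monoculture without TGF-β 2. For DESeq2 and for the falls and rises without single libraries the cause was not tested. EdgeR gave 4975, 387 and 4031 genes, of which 4811, 372 and 3931 were shared. The overlap of 379 genes was 701 with DESeq2, 136 without monoculture 1 and TGF-β 2, and 153 to 658 with each library left out. The covariance was 0.153 to 0.187 in the latter, 0.112 without a filter, 0.264 and 0.0972 with added values of 1 and 50, and 0.359, 0.330 and 0.332 with edgeR, DESeq2 and voom. Lists called (9, 15 and 12) were 0, 0 and 0 with an estimated correlation and 17, 7 and 17 with fry, and 8 to 9, 10 to 16 and 8 to 13 with each library left out. In co-culture against monoculture, lists of alternative activation (adjusted p = 8.07e-05), MHC class II (7.99e-04), glial (2.46e-05), sensory neuron (0.0188), TGF-β pathway (0.00170), Lyve1-high (0.00812), neutrophil (0.00213) and dendritic cell genes (0.00895) passed with fry, glial and sensory neuron genes also without a filter (0.0268 each). Against TGF-β, fry added alternative activation, stress, protease, axon guidance, sensory neuron, endothelial and neutrophil lists and ended cholesterol synthesis and respiratory chain. Fry turned the direction of matrix proteases in co-culture to higher (median -0.14). Against TGF-β, glial markers leaned lower with the 1 CPM filter (median -0.13), and their median was 0.0563 to 0.870 with each library left out. Of 17 markers 10 passed the 1 CPM filter and 11 the filter redone without a co-culture library, since those reaching 10 counts only in co-culture then had 2 libraries; with the same genes tested the list leaned higher in every fit (median 0.734 to 0.870). Replicates of the same number correlated at -0.147 to 0.372 after group means were removed, and those of unlike number at -0.351 to 0.249. With 3 libraries per group these values cannot rule pairing out, and the sex of the donors matched by number. The main test did not treat the replicates as pairs. As a block the number gave 4926, 397 and 3956 genes, and sex gave 4832, 347 and 3886. Thinning all libraries to 46.8 M reads (M, 1e6), the depth of the shallowest, gave 4816, 408 and 3914 genes. An arm of 2 libraries is assumed to vary like the others.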

Other observations

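The families below, the counts of markers that pass the filter outside co-culture, and all tests of the other-sex reads and of depth were chosen after the results had been seen; the splits and the covariance test were set before. Families of related genes beyond the prepared lists also moved together in co-culture. The Ms4a genes, tetraspan membrane proteins of macrophages and microglia, were higher for 7 of 9 members: Ms4a6c went from 5179 to 24224, Ms4a7 from 13286 to 44321 and Ms4a4a from 346 to 10187 (n = 3 each). TGF-β alone raised 5 of them, Ms4a7 to 31557 and, in log2 units, Ms4a6b by 1.09, Ms4a6c by 0.94, Ms4a4a by 0.91 and Ms4a6d by 0.65. The Serpinb genes, intracellular protease inhibitors, were lower for 9 of 10. Serpinb9b, an inhibitor of the granzyme type, fell from 2626 to 7.02, with 826 under TGF-β, and Serpinb2 alone rose (1.65). The annexins, membrane repair and resolution proteins, were lower for 8 of 9, with Anxa1 at 108176 in monoculture and 25602 in co-culture and Anxa3 alone higher (0.86). With camera at a preset correlation over 335 families, adjusted p was 1.13e-05 for Ms4a, 1.18e-05 for Serpinb and 5.95e-04 for annexins; with an estimated correlation it was 0.993 for each.

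The interferon-inducible genes did not move as 1 block. All 6 Oas genes and all 6 Ifit genes were lower in co-culture, with family medians of -1.79 and -2.03. Of 7 guanylate-binding protein genes, which interferon gamma induces most, 5 were higher: Gbp8 (32.0 to 898), Gbp3, Gbp7, Gbp5 (94.6 to 327) and Gbp9. The T cell receptor alpha segments Trav14-3 (195 to 431) and Trav13-4-dv7 (25.1 to 251) were higher in co-culture and not called with TGF-β; 5 more were tested only because co-culture was high. How reads shared by close paralogs were assigned is not stated. With TGF-β the 65 replication-dependent histone genes had a median of 0.52 with 5 called (camera adjusted p = 4.85e-19, 0.888 with an estimated correlation), against -0.03 in co-culture. Ccr2 and the heat-stable antigen Cd24a (1.59 with TGF-β, 0.32 in co-culture) were raised by TGF-β and not called in co-culture.

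The fibroblast and glial transcripts of the co-culture libraries could be carried over from the DRG culture, since ganglia hold such cells, or be made by macrophages. The sort on CD11b and CD64 selects against the cells themselves but could let some of them through. It would not remove RNA that macrophages had taken up or that adhered to them. The lowest Y-linked count in a female co-culture library was 10.2, against at most 2.30 in the female libraries of the other groups, and Xist was 222 in the male co-culture library against 3.25 and 9.77 in the other male libraries. This is consistent with foreign RNA in the co-culture samples, from the DRG culture or from mixing of the co-culture samples with each other, which these values do not tell apart. Mixing among co-culture samples would not by itself bring in Ngfr and Col1a2, which averaged 0 and 28.8 in monoculture. Of the 2590 genes higher in co-culture, 474 were under 10 normalized counts in monoculture; a source outside the macrophages stays open for these and for genes above that level, such as Col1a2, Tmem119 and Thbs1.

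Carried-over RNA was also weighed as a source of the microglia-type genes, where the increases of the 17 risen members summed to 0.448% of co-culture reads, those of all 2590 risen genes to 6.65% and that of Apoe to 0.522%. Reads of the other sex stood at 0.287 to 0.726% in the co-culture libraries, but foreign reads of a library's own sex cannot be seen. The median Y-linked share (0.554%) and the Xist share (0.402%) summed to 0.957%. That is above the increases of the microglia list and of Apoe and below that of all risen genes. The sum assumes that both shares apply to every co-culture library and that foreign cells express these genes like macrophages, which is not known. Amounts alone thus cannot tell for the microglia-type genes. Fcrls and Cx3cr1 rose with TGF-β in cultures without neurons, which shows that these macrophages can raise them. With all libraries thinned to equal total reads the median of the list was 1.94, against 1.95. The rise thus did not need the extra reads of the co-culture libraries. Thinning hardly moves fold changes of well-covered genes already scaled by size factor, so it does not test other effects of depth. A culture with neurons of a marked strain, or single-cell sequencing, would separate the sources of Tmem119 and of the TGF-β target list, Thbs1 included, for which these amounts were not compared and carry-over stays open.

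The covariance of the effects of co-culture and TGF-β was 0.155, against at most 0.0388 in simulations with no effect, in which the control group was simulated too. The spread among the monoculture libraries alone would give 0.0460, above the highest simulation. The simulations drew each gene independently, without variation shared by genes within a library, so they can set the value for shared controls too low. The observed covariance lay above both values, but how much of it comes from shared controls was not settled. A shared TGF-β response fits the same-direction changes of Cx3cr1, Fcrls, Apoe, Lpl and Cd5l. It leaves open whether the larger co-culture changes reflect a higher dose, longer exposure or other signals from the DRG culture, neuronal or not. For genes that rose, carried-over RNA stays open as well. The design holds a single dose of TGF-β and no culture with the other DRG cells alone.

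With 3 libraries against 3 there are 10 splits of the 6, so the share of splits that reach the real count is never under 0.1. For genes it was 1 of 10 in each comparison, with 5033, 412 and 4128 for the real split and 0, 57 and 0 for the highest other. For lists it was 2, 1 and 2 of 10, with 9, 15 and 12 for the real split and 9, 10 and 13 for the highest other. The split with 57 genes set monoculture 1, TGF-β 1 and TGF-β 2 against the rest.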
